A study of Homo sapiens with 12 samples.

How the data were processed

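The series holds m6A-seq and CLIP-seq of HEK293T cells. Per the labels' protocols, polyadenylated RNA depleted of ribosomal RNA was fragmented by sonication, pulled down with an m6A antibody kit and sequenced with a stranded mRNA library kit, and CLIP used ultraviolet crosslinking, RNase T1, anti-Flag beads and a small RNA library kit. The submitters' processing notes name the build hg38 and DESeq2, without a version or a role. The aligner is not given in the sources used here. The 3 tables are the authors' own lists, with no values per replicate. All analyses start from these lists.

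The deposited m6A table has 1 line per differential peak, with exon blocks, a log2 fold change between conditions, a fold enrichment of pulldown over input, and logarithms of p-values, per the file headers. Its largest adjusted p is at the threshold of 0.05, so only peaks past it are listed. The sign convention is not stated per the file headers. The deposited TRMT10A table is a list of sites, annotated in the column layout of HOMER, with a peak height as the score of each site and a p-value (at most 0.0494) inside the peak name. It does not separate the 3 libraries, so the authors' sites were taken as pooled. The deposited FTO table lists clusters per transcript with a count of conversion events, per the file headers. In 2 of its 7628 transcript lines the list stops after 145 clusters, and the remaining clusters of XIST and RNA28S5 were not analysed here. The score of a peak is the authors' and was used only to rank or filter peaks within its own list.

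Gene names came from a table of GRCh38.p14 genes, the assembly of which hg38 is the primary build. Of the m6A peaks, 1890 matched a current symbol, 116 an older symbol and 17 none. Entrez identifiers matched for 6566 of 6571 TRMT10A lines, and 18942 of 19163 FTO entries matched. The 6571 TRMT10A lines describe 5650 distinct sites. A site was given the gene in its peak name where the span of that gene holds it (86.3% of lines), and otherwise the gene of the annotated transcript. Sites in ribosomal, transfer or other small RNA genes were counted for those RNAs and not for their host genes. Coordinates are hg38, counted from 1.

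Overlaps needed at least 1 shared base on the same strand, and the count of shared FTO clusters equalled that of bedtools 2.31.1. Expected overlaps came from 1000 random placements in the span of the same gene (100 placements for the setting that asks for 0.5 of the shorter interval). Shares carry 95% Wilson intervals, which cover counting error only. Shares were compared with two-sided Fisher's exact tests, and medians over genes with two-sided permutation tests of 100000 resamples. Benjamini-Hochberg adjustment was made over the 3 binding classes within each setting, over both proteins for m6A peaks, and over the 44 tests of 11 coding gene lists in 4 gene sets. A further 4 noncoding lists were counted only. Stratified odds ratios are Mantel-Haenszel estimates over 5 strata. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

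Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Most genes named in the text were drawn by this rule. It took the 10 largest positive and negative m6A values with 1 peak per gene. From each CLIP list it took the 10 genes of the highest sites and the 5 genes with the most sites. It also took the 10 largest positive values among genes with sites of both proteins. Up to 4 members per gene list and table, and TRMT10A and FTO, completed it. Not drawn by it were RACK1, ACTB and ACTG1, host genes of tRNAs, and genes that entered only by a ranking among protein-coding genes. Increased and decreased in that plan are given here as positive and negative. The plan named a count model if values per library were given. They were not in these tables, so peaks were counted. Tests on codons and on sequence motifs were planned and not run, since no genome or coding sequence was used here.

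The steps were tested on simulated data before use. With 200 shared clusters planted among 8482, the overlap step recovered a mean of 197 and passed its threshold in 100% of 50 simulations, and in 0% with none planted. The other clusters were drawn in the same way as the random placements. The 0% therefore checks the computation and does not cover a preference of both proteins for exons. For the share of bound genes, over 1736 genes and 5000 simulations, 4.84% passed at a planted odds ratio of 1 and 96.9% at 1.5. For medians over 1786 genes, 4% of 50 simulations passed with no shift and 100% with a shift of 0.5 on the log2 scale.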

Results

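HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, were profiled by m6A-seq after knockdown of TRMT10A, and by CLIP-seq of TRMT10A and of FTO. TRMT10A is a methyltransferase that forms 1-methylguanosine at position 9 of tRNAs, and FTO removes methyl groups from N6-methyladenosine (m6A), a modified base of mRNA. In m6A-seq, fragments of polyadenylated RNA are pulled down with an antibody against m6A and sequenced beside an input that was not pulled down. The m6A groups were the pulldown and the input from cells given TRMT10A siRNA or control siRNA, with 2 samples in each. In CLIP-seq, cells that overexpressed the protein were irradiated with ultraviolet light and the crosslinked RNA was recovered, with 3 samples for TRMT10A and 1 for FTO. None of the authors' tables gives values for single m6A or TRMT10A samples. Read depth per sample is therefore unknown, and spread between replicates could not be measured. Tests below treat genes or sites as the units and describe these tables. They carry no replicate error, and genes are not independent replicates.

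The first comparison asks which m6A peaks differ between TRMT10A knockdown and control. The authors' deposited table holds 2023 differential peaks in 1786 genes, 1346 of them with a positive and 677 with a negative log2 fold change. Positive peaks made up 66.5% of the total (95% Wilson interval 64.4 to 68.6%, counting error only). The headers of the authors' deposited table do not state which condition is the numerator. Signs are therefore given as in that table, and positive can be read as higher in the knockdown only if the usual order of treated over control was kept. The median log2 fold change in the authors' deposited table was 0.70 for positive peaks and -0.52 for negative peaks. At an absolute log2 fold change of at least 1 there were 376 positive and 84 negative peaks, so that the positive share was 81.7%.

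The knocked-down gene had 1 peak. In the authors' deposited table the TRMT10A transcript had a log2 fold change of 1.48 (adjusted p = 3.98e-19), over 7 exon blocks of chromosome 4 from 99548806 to 99559327 in hg38. FTO had no differential peak. The largest positive values of the authors' deposited table were at EIF3CL (9.80), LINC01123 (9.12) and EIF3C (8.87), followed by SMN1 and SMN2 (8.83 at a single shared position). EIF3C and EIF3CL encode subunits of a translation initiation factor, and SMN1 and SMN2 are near-identical copies needed for assembly of spliceosomal particles. Next in the authors' deposited table came RNA28S5 (6.39), RNA45S5 (6.32), STAG3L2 (5.78) and CBS (5.58), of which the first pair are ribosomal RNA genes. The largest negative values in the authors' deposited table were at WASHC1 (-7.90), NOMO2 (-7.55), MAGEA2B (-7.03) and LOC728554 (-5.68). TRAPPC4 (-4.06), CSAG3 (-4.04), FAM27B (-3.65), BOLA2 and BOLA2B (-3.53 each) and CKMT1B (-3.42) completed the negative end of the authors' deposited table. Several of these genes have near-identical copies elsewhere in the genome. Of the 25 peaks with an absolute log2 fold change of at least 3 in the authors' deposited table, 14 were marked as lying on repeated copies. A position listed under several gene names counts once per name here. SMN1, for example, had 8.83 at one copy and -2.60 at the other in the authors' deposited table.

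Some genes of the m6A machinery and of tRNA biology had differential peaks, but neither the m6A machinery (adjusted p = 1 for positive and for negative genes), tRNA modification enzymes (0.382 and 0.89) nor aminoacyl-tRNA synthetases (0.89 and 1) differed detectably from other genes of the tables (Fisher's exact test). Of the m6A writers, erasers and readers, 5 had peaks. In the authors' deposited table the reader YTHDF2 had a log2 fold change of 2.36, the reader and helicase YTHDC2 -1.13 and the writer subunit WTAP -0.42. The demethylase ALKBH5 had 2.23 and 0.88 at its 2 peaks in the authors' deposited table, and the smaller value had the lower adjusted p. Of the tRNA modification enzymes, 8 had only positive and 3 only negative peaks. The 8 include TRMT10A, the knocked-down gene. Values in the authors' deposited table were 2.26 for the deaminase subunit ADAT3, 1.56 for the 7-methylguanosine methyltransferase METTL1 and 1.13 for HSD17B10, a subunit of mitochondrial RNase P. Among aminoacyl-tRNA synthetases, FARSA had 2.21 and EPRS1 -0.91 in the authors' deposited table, and MARS had peaks of both signs (0.89 and -0.59). C2H2 zinc finger genes made up 37 of the genes with only positive peaks and were more frequent there than other genes (38.5% of 96 against 21.2%, odds ratio 2.33, Fisher's exact test, two-sided, adjusted p = 0.00118). The authors' deposited table gave 2.84 for ZNF865, 2.74 for ZNF696, 2.31 for ZNF837 and 2.12 for ZFP91. Cytosolic ribosomal protein genes were rare among genes with only positive peaks (1 of 76 against 21.9% of other genes, odds ratio 0.0477, adjusted p = 6.78e-06). FAU had 0.48 in the authors' deposited table, while RPL4 (-0.29), RPL13 (-0.27) and RPS24 (-0.13) had small negative values. The background of both calls was protein-coding genes with a peak in any of the 3 tables. It raises the m6A share of lists with few CLIP-bound genes and lowers that of lists with many. FTO clusters were found in 37.5% of the C2H2 zinc finger genes and 97.4% of the ribosomal protein genes. Both calls can therefore follow from the background. Neither call held with all protein-coding genes as background. Translation factors (Fisher's exact test, adjusted p = 0.0012), integrated stress response genes (adjusted p = 0.00123) and tRNA modification enzymes (adjusted p = 0.0482) passed in their place. The call for tRNA modification enzymes counts the knocked-down TRMT10A and was not repeated without it. No list passed among genes with only negative peaks at an adjusted p of 0.05, and histones alone had an unadjusted p below it, as a lower share (1 of 51 against 11.3% of other genes, Fisher's exact test, p = 0.04). None of the 11 tested lists differed in the split between positive and negative genes (Fisher's exact test, lowest p = 0.0504 before adjustment, for ribosomal proteins with 1 positive and 4 negative genes, and 0.555 after it).

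Among other lists, histones (4 of 51 against 21.7% of other genes, Fisher's exact test, adjusted p = 0.0678) and histone lysine methyltransferases and demethylases (3 of 29 against 21.6%, adjusted p = 0.382) had lower shares of genes with only positive peaks, neither past the threshold. In the authors' deposited table the linker histone H1-10 had a log2 fold change of 1.40 and H2AJ 1.19. SETD1A (1.83) and KDM5C (0.94), which write and erase lysine methylation on histone H3, were positive in the authors' deposited table, and NSD2 had peaks of both signs (-1.40 and 0.49). Of genes described elsewhere as FTO targets, CCND1 had 1.48, UHRF1 1.02, MYC 0.98 and PKM -0.16 in the authors' deposited table. Of integrated stress response genes, 6 had positive peaks and 1 negative, and the authors' deposited table gave 0.49 for SLC3A2, 0.45 for PPP1R15A, 0.36 for DDIT4 and -0.74 for TRIB3. LMNB2 (0.34 in the authors' deposited table) was the 1 primary microcephaly gene with a peak.

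The TRMT10A CLIP list held 5650 distinct sites, of which 5400 (95.6%) were in protein-coding genes, 88 in long noncoding RNAs, 47 in ribosomal RNA and 22 in tRNA genes. Of the protein-coding sites, 64.6% (95% Wilson interval 63.3 to 65.9%) lay in coding exons, 14.4% in 3' UTRs, 12.1% in introns and 3.43% in 5' UTRs. Sites fell in 2649 genes. FLNA, an actin crosslinker, had the most in a protein-coding gene (22), followed by the fatty acid synthase FASN (21), PARP1 and PRRC2B (20 each) and SBF1 (19). The peak height, the authors' own score, was used here only to rank and filter sites within this list, and ran from 16 to 125 with a median of 20. Ribosomal RNA held the highest site (125, at 8216949 of chromosome 21). The 47 ribosomal RNA sites had a median height of 112. All lay in the 45S array of chromosome 21, whose repeated units were counted separately. Ranked by the highest site of each gene, with the ribosomal RNA array as 1 entry, the next were intronic. They were at GREB1, SLCO5A1, HFM1, PID1, MED12L, PDE3A, RYR2, ANKRD30BL and AAMDC, with 121 at HFM1 and PID1 and 118 at AAMDC. Whether these intronic positions resemble ribosomal RNA in sequence was not tested, since no genome was used here. The TRMT10A transcript, overexpressed in these cells, had 7 sites, all in coding exons, with heights of 55 to 84. Heights of at least 55 were reached by 3.17% of all sites.

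TRMT10A sites covered 21 tRNA genes with 14 different amino acid letters in their names, at a median height of 58 against 20 for the whole list. The highest were at the histidine tRNA genes TRH-GTG1-7 (105, chromosome 15 from 45198653 to 45198655) and TRH-GTG1-8 (103), inside the span of SHF. TRG-CCC6-1 (77), TRP-CGG1-3 (74) and TRG-GCC3-1 and TRG-GCC2-4 (70 each) followed. No glutamine tRNA gene was among them. The sites were listed under host genes such as SHF, VAC14 and KCTD2, so tRNA genes outside any annotated gene were possibly not searched, and the 465 tRNA genes of the gene table are no background for a share. Among mRNAs of translation, heights reached 81 at RPS23, 76 at the elongation factor EEF2 and 68 at RPL15. Ribosomal protein genes were TRMT10A-bound more often than other genes of the tables (53 of 76 against 49.4%, odds ratio 2.36, Fisher's exact test, adjusted p = 0.00338), and so were translation factors (32 of 44 against 49.5%, odds ratio 2.72, adjusted p = 0.0141). C2H2 zinc finger genes were bound less often (28 of 96 against 50.1%, odds ratio 0.41, adjusted p = 0.000526). Expression level was not measured here, so these shares cannot tell a binding preference from transcript abundance. Of the m6A machinery, 11 genes had a site, with heights of 47 at HNRNPA2B1 and IGF2BP1 and 39 at ALKBH5, which had 14 sites. Heights were 45 at PHGDH and 36 at ATF4, an enzyme of serine synthesis and the main transcription factor of the integrated stress response.

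The FTO CLIP list, from 1 library, held 9579 distinct clusters, and 7977 (83.3%) of them were in protein-coding genes. Ribosomal RNA held 464 clusters and 85.5% of all conversion events, small nucleolar RNAs held 363 clusters, long noncoding RNAs 342, small nuclear RNAs 98 and tRNA genes 6. Of the ribosomal RNA clusters, 439 lay in the 45S array of chromosome 21. Repeated units of the array were counted separately, so a position can count once per unit. Of the protein-coding clusters, 59.2% (58.1 to 60.3%) lay in coding exons and 28.4% (27.4 to 29.4%) in 3' UTRs. The 3' UTR share of TRMT10A sites was 14.4% (13.5 to 15.4%). The lists came from different peak callers, so this difference is between lists. Conversion events, which count base changes at crosslinked positions, ranged from 2 to 31115 per cluster with a median of 3. Outside annotated ribosomal RNA genes, by the highest cluster of each gene, the most were at introns of PDE3A (4320), ANKRD30BL (3566), HFM1 (3419) and SLCO5A1 (3312). Their likeness to ribosomal RNA was likewise not tested. Next came the spliceosomal RNA gene RNU1-4 (1912) and the small nucleolar RNA SNORD49A (1898). XIST had 145 listed clusters and MALAT1 80, both long noncoding RNAs of the nucleus, and the XIST entry ends before all of its 275 stated clusters are listed. Among protein-coding genes MYH9 (40), SCD (37), SRRM2 (36), DDX17 (33) and AMOT (32) had the most clusters. The FTO transcript had 3 clusters with 2 to 6 conversion events, and TRMT10A had none. FTO clusters were found in 74 of 76 ribosomal protein genes (60.4% of other genes, odds ratio 24.3, Fisher's exact test, adjusted p = 2.83e-12) and in 16 of 17 genes of the m6A machinery (60.8% of other genes, odds ratio 10.3, adjusted p = 0.0248). The 16 include FTO itself, which was overexpressed in these cells. C2H2 zinc finger genes were FTO-bound less often (36 of 96 against 61.4%, odds ratio 0.378, adjusted p = 5.58e-05). As for TRMT10A, these shares were not adjusted for expression level. EEF2 had 29 clusters, with up to 126 conversion events, and the chaperone gene HSPA5 had 28.

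**Figure D1:**
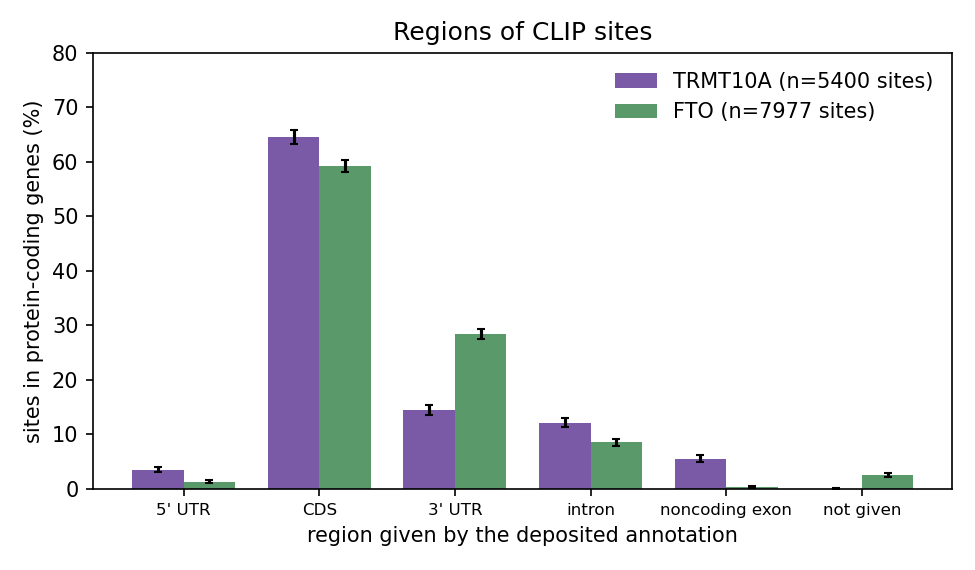
Share of CLIP sites in protein-coding genes (y axis, %) by the region given in the deposited annotation (x axis), for 5400 TRMT10A sites and 7977 FTO clusters, with 95% Wilson intervals as error bars. Coding exons hold 64.6% of TRMT10A sites and 59.2% of FTO clusters, and 3' UTRs hold 14.4% and 28.4%.

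The next comparison asks whether both proteins were crosslinked at the same places. Outside ribosomal and small RNA genes, 666 of 8482 FTO clusters (7.85%) shared at least 1 base with a TRMT10A site on the same strand, in 481 genes. When each cluster was placed at random in the span of its own gene, a mean of 55 ± 7.23 clusters (SD over 1000 placements) did so, a ratio of 12.1 (one-sided permutation p = 0.001, the smallest these placements can give). None overlapped on the opposite strand. Random placement gave almost none there either, with a mean of 55.3 without regard to strand, so this absence says little about specificity. With a gap of up to 100 bases allowed, 1809 clusters were counted, 5.3 times the mean of random placements. Gene spans include introns, and the ratio was 5.76 when each cluster was instead moved by 50 to 200 bases. Coding exons held 454 of the 666 shared clusters and introns 76. The intronic ones carried 83.3% of the conversion events of shared clusters and can include the untested positions named above. Without intronic sites 589 of 7743 clusters were shared, 5.89 times the mean after such a move. Moved clusters were not held to exons and can land in introns. These ratios therefore do not remove a shared preference for exons. Shared exonic sites with the highest TRMT10A heights, a choice made after the values were seen, were at the ribosomal scaffold RACK1 (95, chromosome 5 at 181239113), the histone gene H3C2 (84) and the actin genes ACTB (82) and ACTG1 (80), all in coding exons. Of the 6 tRNA genes with an FTO cluster, 5 also had a TRMT10A site, among them TRH-GTG1-7 and TRG-GCC3-1.

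**Figure D2:**
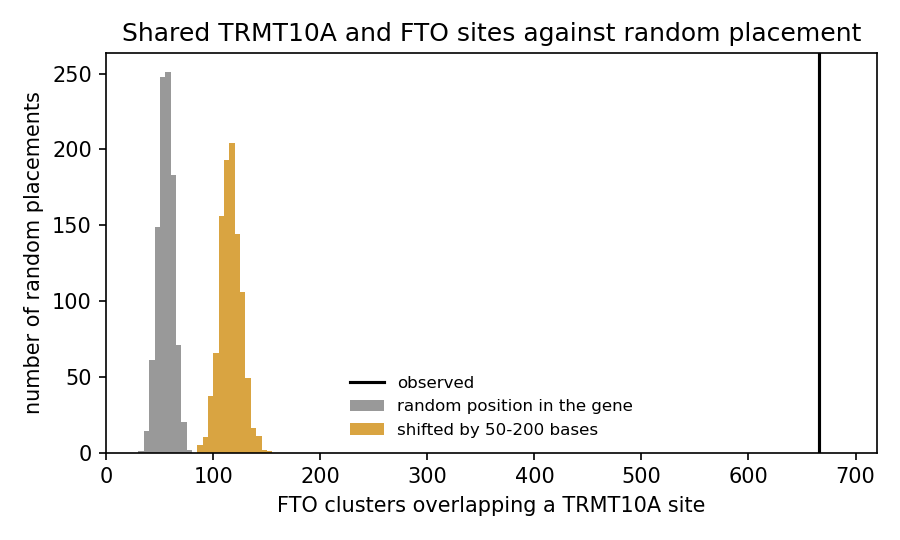
Number of FTO clusters that overlap a TRMT10A site (x axis) over 1000 random placements (y axis, number of placements), for positions drawn from the whole gene (grey) and for moves of 50 to 200 bases (yellow). The line marks the 666 observed clusters, which are 12.1 times the grey mean of 55 and 5.76 times the yellow mean.

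At the level of genes, 1394 protein-coding genes had sites of both proteins. Against the background fixed beforehand, protein-coding genes with a peak in any of the 3 tables, this was fewer than the 1542 of independent lists (odds ratio 0.611, Fisher's exact test, two-sided, p = 1.72e-17). That background holds few genes bound by neither protein, and the direction turned with the other backgrounds. The odds ratio was 11.3 over all 20052 protein-coding genes and 5.08 (Fisher's exact test, p = 2.62e-52) within the 1716 protein-coding genes of the m6A table. In the latter, 63.4% of TRMT10A-bound genes were FTO-bound, against 25.4% of the others. For sites above the median score the odds ratio was 2.62 (Fisher's exact test, p = 1.68e-39) against the first background.

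The design then links binding to methylation. Of genes with only positive m6A peaks, 414 of 1139 (36.3%, 95% Wilson interval 33.6 to 39.2%) had a TRMT10A site, against 143 of 597 (24%, 20.7 to 27.5%) of genes with only negative peaks (odds ratio 1.81, Fisher's exact test, two-sided, adjusted p = 3.26e-07). FTO went the other way, with 34.7% of positive against 40.5% of negative genes (odds ratio 0.779, adjusted p = 0.0274). The TRMT10A odds ratio was 2.32 times that of FTO (p = 0.0001 by permutation of the signs over genes, the smallest 10000 permutations can give). Genes with sites of both were at 21.6% and 17.4% (odds ratio 1.31, adjusted p = 0.0438). Genes bound by TRMT10A and not FTO were at 14.7% and 6.53%, and genes bound by FTO and not TRMT10A at 13.1% and 23.1%. The FTO call ended with an absolute log2 fold change of at least 1, with CLIP sites above the median score, with genes assigned by coordinates and with strata of gene span, and over its 8 alternatives the adjusted p ran from 0.00647 to 0.781. The call for both proteins ended in 6 of its 10 alternatives (adjusted p from 0.023 to 0.357), and that for TRMT10A in none of 10 (adjusted p from 1.13e-07 to 0.0368).

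**Figure D3:**
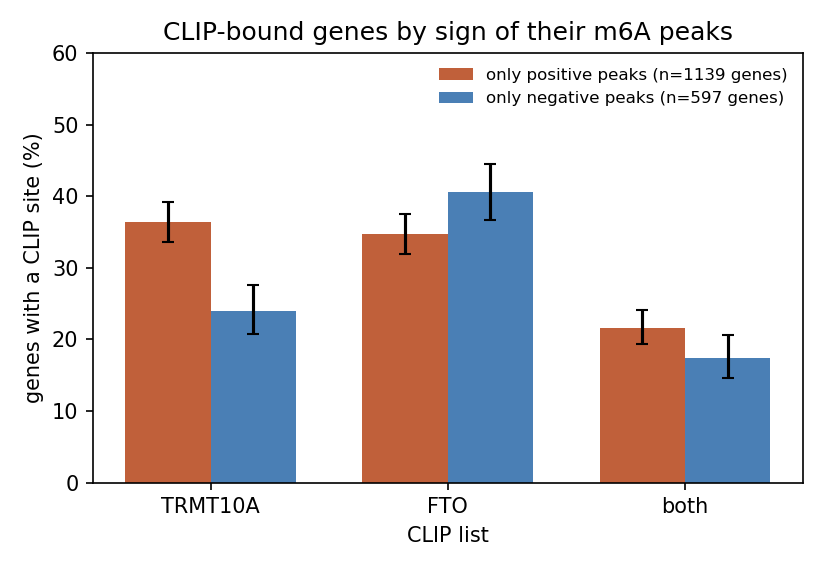
Share of genes with a CLIP site (y axis, %) for TRMT10A, FTO or both (x axis), in 1139 genes with only positive and 597 genes with only negative m6A peaks, with 95% Wilson intervals. TRMT10A-bound genes make up 36.3% and 24%, FTO-bound genes 34.7% and 40.5%.

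On the continuous scale TRMT10A binding made no detectable difference. The median of the mean log2 fold change per gene, computed from the authors' deposited table, was 0.47 for 580 TRMT10A-bound genes and 0.44 for 1206 others (difference 0.03, two-sided permutation test with 100000 resamples, adjusted p = 0.367). FTO-bound genes had a lower median than others (0.34 against 0.52, difference -0.18, adjusted p = 3e-05). With sites of both proteins the difference was -0.06 (adjusted p = 0.316). For TRMT10A the share test passed its threshold and the median test did not. Among genes bound by both proteins, the largest values in the authors' deposited table were at EIF3CL (9.80) and CBS (5.58), both on repeated copies, then PFN1 (3.23), TNRC18 (2.75), NECTIN2 (2.64) and OBSL1 (2.58). PPP4C (2.46), YWHAQ (2.42), YTHDF2 (2.36) and ALKBH5 (2.23) followed in the authors' deposited table.

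Within transcripts, CLIP sites lay inside differential m6A peaks more often than under random placement in the same gene. Of 5543 TRMT10A sites 402 did so, which was 3.96 times the mean of 1000 placements, and of 8482 FTO clusters 626, which was 3.39 times (one-sided permutation p = 0.001 for each, the smallest these placements can give). Gene spans include introns, while m6A peaks are exonic. A TRMT10A site was found in 16.9% of 1346 positive peaks and 8.57% of 677 negative peaks (odds ratio 2.18, Fisher's exact test, two-sided, adjusted p = 3.25e-07). FTO clusters were found in 211 positive (15.7%) and 143 negative peaks (21.1%, odds ratio 0.694, adjusted p = 0.00288). Negative peaks lay nearer the 3' end of their genes, as given below. Neither odds ratio was stratified by position, so position along the gene was not separated from sign here.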

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

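No paired analysis was possible because the tables hold no values per library, so neither a replicate block nor leaving out a replicate could be run. Also not run, for want of a genome and exon annotation, were placement within exons and the alternatives for codons and motifs. Settings chosen after seeing the data are the removal of repeated copies and of overlapping peaks, moved clusters, removal of intronic sites from the site overlap, the m6A-table background, gene assignment by peak name or nearest gene, and all stratified estimates. Of 71 settings tried over all results, 49 left the direction and threshold side, or a count or share, as they were within fixed limits. The TRMT10A share result was among them, under each of its 10 settings. Positive m6A peaks numbered 376 and negative ones 84 at an absolute log2 fold change of at least 1, and negative ones 415 at an adjusted p of 0.01, since fewer peaks pass stricter thresholds. The positive share was 81.7% and 68.9% at those thresholds. For sites above the median score the 3' UTR share was 11.6% for TRMT10A and 26.2% for FTO, and the cause was not tested. The overlap of bound genes turned from an odds ratio of 0.611 to 11.3 with all protein-coding genes, 5.08 with genes of the m6A table and 2.62 with sites above the median score. The first change follows from adding genes bound by neither protein. In the others too, genes without a TRMT10A site were less often FTO-bound. Their share was 25.4% with genes of the m6A table and 16.6% with sites above the median score, against 66.7% at first. No further cause was tested. For FTO-bound genes the odds ratio lost its call at 0.92 with larger fold changes, 0.837 with higher scores, 0.82 by coordinates and 0.817 stratified by gene span. For genes bound by both it did so at 1.62 with larger fold changes, 1.27 with higher scores, with exonic sites (1.27) and without repeated copies (1.27), at 1.19 with the nearest gene and at 1.28 stratified by fold enrichment. The cause was not tested. With all protein-coding genes as background, 9 lists passed for TRMT10A and 9 for FTO, in place of 3 and 3. For positive m6A genes the count went from 2 to 3, but both lists lost their call and 3 different ones passed.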

Other observations

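Tests of peak position and repeated copies and the stratified odds ratios below were added after the data were seen, and those of FTO binding and repeated copies after their own results were seen. Several noncoding RNAs were not described above. Of the small structured RNAs, 7 had a TRMT10A site and 287 an FTO cluster. The highest TRMT10A height among them was 114, at SNORD3A, the U3 small nucleolar RNA. Nuclear genes that resemble mitochondrial 16S ribosomal RNA had sites of both proteins, with a TRMT10A height of 76 at MTRNR2L2 and 290 FTO conversion events at MTRNR2L8. NEAT1, the scaffold of paraspeckles, had 15 FTO clusters and 2 TRMT10A sites. Of 4 listed long noncoding RNAs in the authors' deposited table, XIST (-1.02 at the largest of 5 peaks, all negative) and TUG1 (-0.37) had negative log2 fold changes, and NORAD (0.42) and MALAT1 (0.28) positive ones.

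Negative m6A peaks lay nearer the 3' end of their genes than positive ones, with a median position of 0.856 against 0.527 of the gene span. The last 10% of the span held 43.7% of negative and 21.9% of positive peaks (odds ratio 0.361, Fisher's exact test, p = 3.16e-23). The odds ratio stratified by gene span with introns was 0.429 (95% interval 0.349 to 0.529) and by peak width 0.374 (0.305 to 0.457), which argues against either as the whole cause. A difference between genes alone would not order peaks within a gene, yet in 39 of 42 genes with peaks of both signs (92.9%, exact binomial p = 5.63e-09) the negative peak was the nearer to the 3' end, with 7 of the 50 such genes left out for repeated copies and 1 for want of a position. Coverage towards the 3' end that differs between libraries may give the same pattern and stays open, as does an effect of the knockdown, since no coverage per library was analysed here.

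Genes with positive m6A peaks were more often TRMT10A-bound. Gene span with introns (stratified odds ratio 1.83, 95% interval 1.46 to 2.3) and the position of the m6A peaks (1.93, 1.52 to 2.44) do not account for it. Transcripts that crosslink easily to any protein would raise the FTO share too, and its odds ratio was 0.779, though the FTO call is lost under several settings. The FTO list came from 1 library and another peak caller, and held a larger share of 3' UTR sites. It is no neutral control, so the comparison cannot exclude easy crosslinking. Transcript length without introns, expression level and GC content stay open, because none of them could be measured here. The unstated numerator leaves open whether these genes gained or lost methylation. The difference of 0.03 in the median log2 fold change, and of 0.07 with the largest peak per gene, mixes both signs and is no test of the sign alone.

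Many of the largest m6A fold changes were marked as lying on repeated gene copies. The mark was given to peaks that overlap a peak of another gene or lie outside the span of their gene. All peaks of genes with a distant peak were marked too. Of peaks with an absolute log2 fold change of at least 3, 56% were marked as such, against 3.15% of other peaks (odds ratio 39.1, Fisher's exact test, p = 1.28e-14). SMN1 and SMN2 share a single position, as do BOLA2 and BOLA2B, so these pairs were marked by definition. The test counts each name as a separate peak, although such pairs are not independent. Reads split between near-identical copies are a candidate explanation. The mark uses positions and not sequence, so copies such as NOMO2 and WASHC1 escaped it. Genes that overlap without being copies can carry it. No biological explanation was tested.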
